A study of Mus musculus with 6 samples.

How the data were processed

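RNA sequencing of 6 libraries was examined, 3 from lungs of pups whose dams had received control IgG and 3 from pups whose dams had received 5E1, a monoclonal antibody that binds hedgehog ligands. Per the labels' protocols, pregnant dams carrying a Pdgfra-EGFP reporter allele were injected intraperitoneally at embryonic day 18.5. Lungs of reporter pups were taken at postnatal day 8 and dissociated, live EGFP-positive cells were sorted, and libraries were made with a stranded poly(A) kit. Each library's group and replicate number come from its title. Sample numbers in the titles run through the IgG libraries first and then the 5E1 libraries, so group follows sample number. No label says whether that number gives the order of handling. If it does, order and antibody cannot be told apart. The labels do not say whether the 3 libraries of a group come from separate pups, pools or litters, so p-values measure only the spread between these samples.

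The deposited files hold raw read counts per gene symbol, 1 file per library, with 48397 symbols and 5 HTSeq summary lines each. Per the submitters' processing notes, STAR 2.5.0c, Picard 1.126, bedtools 2.17.0, HTSeq 0.6.0, DESeq2 1.10.0 and R 3.5.1 were used with build mm10, with no role or order given. The gene annotation, the strand setting and the handling of duplicate reads are not given in the sources used here. The summary lines name no gene and were left out of library sizes and tests. They show that unaligned reads took 20.4% to 42.9% of a library, reads with more than 1 alignment 5.27% to 6.26%, and reads ambiguous between genes 1.94% to 2.66%. Reads in no annotated gene took 7.70% to 10.8% of uniquely aligned reads.

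Gene counts summed to 28405457, 16958433 and 25847058 for IgG replicates 1 to 3 and to 18857199, 34318583 and 30268765 for 5E1 replicates 1 to 3. Between 21118 and 22910 symbols had at least 1 read in a library. All pairs of replicates within a group differed by more than sampling noise, with chi-square over degrees of freedom of 14.8 to 50.5, so no library was counted as a copy of another. Symbols were matched to GENCODE release M21, built on GRCm38 (mm10), for positions, transcript length and GC content. Of the 16198 genes tested, 15711 (97.0%) matched. Exons of 42 of the 186 genes chosen for naming overlap an exon of another annotated gene. These include Gli1 (327 bases with Arhgap9 and Gm47200, both on the opposite strand), Hhip (175 bases), Tagln (1349 bases, with Pcsk7 among others) and Eln (267 bases). Because the strand setting and the annotation are not stated, their counts may hold reads of the overlapping gene. They may also lack reads that were counted as ambiguous between genes. Stfa2 and Stfa2l1, the alpha and beta globin genes and the ribosomal protein genes have near-identical copies or pseudogenes. Their values are uncertain too, since reads with more than 1 alignment were counted apart from genes.

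Genes were kept with filterByExpr at its defaults (minimum count 10, minimum total 15). Counts were scaled by the trimmed mean of M-values (TMM) and fitted in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, group as the only term). P-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 was called. Tests are two-sided. Levels are CPM, normalised read counts on TMM-scaled library sizes, given as mean ± SD over 3 libraries. Log2 fold changes are 5E1 over IgG with a prior count of 0.125, and the standard error (SE) is the unshrunken coefficient over the square root of the F statistic. Gene lists, 44 in all with 992 symbols of which 2 are not in the files, were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same applies to the choice of main test and to the rule for naming genes.

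That rule always names Gli1, Ptch1, Hhip, Foxf1, Pdgfra, Acta2, Tagln, Eln and Tcf21. It then takes the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM whose 5E1 libraries all lie on one side of the IgG libraries, skipping unnamed gene models. Last, it takes up to 4 members of each list with the smallest p, and the most abundant members of lists of other cell types. Some genes that the rule takes are not reported here. Other genes are named only to complete a small count, and are then said to have been chosen after their values were seen. Where a group had 0 reads, the fold is a bound against a floor of 3 reads over the group's 3 libraries. Counting intervals are exact binomial intervals at 95%, and both cover counting error only, since reads are not independent molecules.

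Alternatives were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, no low-count filter beyond 1 read in total, a filter of at least 5 CPM in 3 libraries, no robust estimation, the replicate number as a block, each library left out in turn and other thresholds. For lists, camera with an estimated correlation and the rotation test fry, directional and mixed, were run too. Sex-linked, erythroid and leukocyte markers were left out in a further run. Chosen after seeing the data were a term for the libraries without Y-linked reads, offsets that remove each library's trend with transcript length and GC content (mgcv 1.9.3), and a run without the 20 most abundant genes.

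The steps were tested on simulated data, with counts drawn from the means and sizes of these 6 libraries for 15872 tested genes. Among 50 genes changed at each size, the test recovered 46% at 1.5-fold, 70% at 2-fold, 82% at 4-fold and 90% at 8-fold. Of its calls, 12.7% (21 genes) were false, above the nominal 5%. None of 40 unchanged lists and both changed lists were called. Simulated genes were drawn independently, so the list result does not cover lists with correlated members. In the data the estimated correlation reached 0.922, for G2 and mitosis genes. A far smaller share of genes was changed than in the data, so the false share may not carry over.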

Results

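Cells that carried a green reporter for Pdgfra, a PDGF receptor gene of lung mesenchyme, were sorted from mouse lungs at postnatal day 8 and profiled by bulk RNA sequencing. Their dams had received either the hedgehog-binding antibody 5E1 or control IgG late in gestation, giving 3 libraries per group. The series title places the comparison in the question of how hedgehog signalling relates to PDGF signalling when alveolar septa form. Reads assigned to genes numbered 16958433 to 28405457 per IgG library and 18857199 to 34318583 per 5E1 library.

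In bulk RNA, expression per cell cannot be told apart from the mix of cells sorted. Within that limit, sorted cells from 5E1-exposed pups gave relatively fewer reads of hedgehog targets and of contractile, cell cycle and cholesterol synthesis genes. They gave relatively more reads of elastin, of adventitial fibroblast genes, of immediate early genes and of leukocyte markers. None of these lists was called with an estimated correlation between members, the adjusted p being 0.0663 for hedgehog targets and 0.339 for the others. Of 16198 genes tested, 3757 (23.2%) changed, 1966 of them higher and 1791 lower in 5E1, and 1289 changed at least 2-fold (801 higher, 488 lower). The first principal component held 57.3% of the variance and parted the 3 IgG from the 3 5E1 libraries. With library size alone in place of TMM the split was 1312 higher and 3274 lower, so 28.6% of calls were higher instead of 52.3%, and the median log2 fold change of all genes moved by -0.14. Fewer genes were called without IgG replicate 1 (2497), 2 (2305) or 3 (2517) or without 5E1 replicate 1 (3704), 2 (3489) or 3 (2410).

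**Figure D1:**
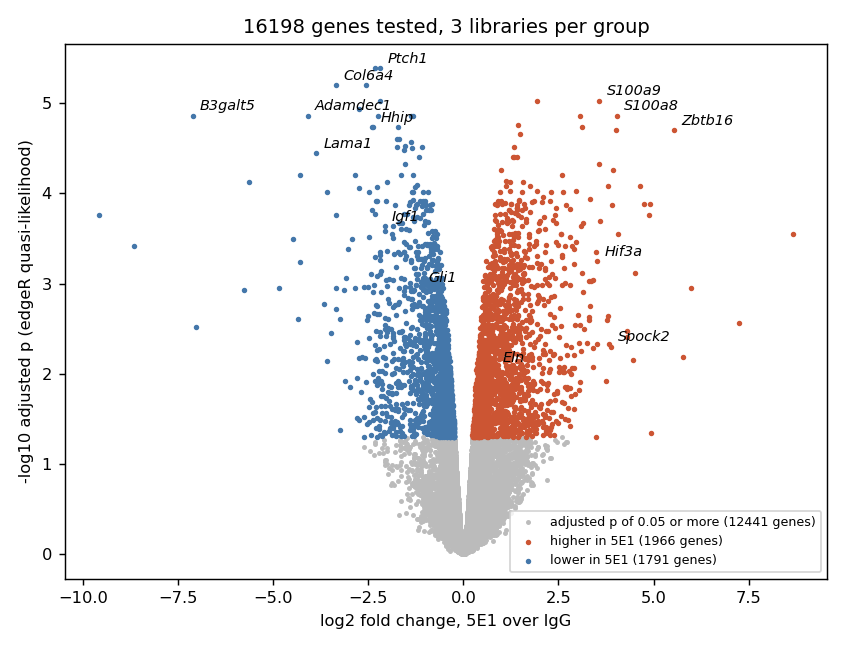
Each point is a gene, with the log2 fold change of 5E1 over IgG on the horizontal axis and -log10 of the edgeR adjusted p on the vertical axis. The 1966 genes called higher in 5E1 are red, the 1791 called lower are blue, and positions of genes near 0 reads in one group are fitted values.

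The gene raised most under the naming rule was Zbtb16, which encodes a zinc finger transcription factor. Its level was 1.56 ± 0.410 CPM in IgG and 71.5 ± 18.2 CPM in 5E1 (SD, n = 3 each), 46.5-fold higher, with an edgeR adjusted p of 2.01e-05. S100a8 (16.3-fold) and S100a9 (11.9-fold), which encode the calprotectin subunits abundant in neutrophils, followed together with Stfa2 (15.3-fold), Stfa2l1 (11.8-fold) and Retnlg (12.2-fold). Spock2, a proteoglycan gene on the list of type 1 alveolar epithelial markers, rose 14.7-fold, and Hif3a, a member of the hypoxia-inducible factor family, rose 11.5-fold. Among the lowest, B3galt5, a galactosyltransferase gene, had 954 reads over the IgG libraries and 7 over the 5E1 libraries. Its pooled level was 144-fold lower, with a counting interval of 69.8 to 360. Adamdec1 (17.01-fold lower), Lama1 (14.6-fold), Otof (12.8-fold), St6gal2 (12.1-fold), Col6a4 (10.1-fold) and Sez6l (8.45-fold) also fell, the edgeR adjusted p being at most 0.00167. Kif18b, a mitotic kinesin gene, was 6.89-fold lower with an edgeR adjusted p of 0.0311. Without IgG replicate 1, 2 or 3, or without 5E1 replicate 3, its adjusted p lay between 0.0811 and 0.111, and with no low-count filter it was 0.116.

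Hedgehog targets give the direct readout of the antibody. Ptch1, the receptor gene that pathway activity induces, fell from 411 ± 4.92 CPM in IgG to 90.1 ± 10.4 CPM in 5E1 (SD, n = 3 each). Its log2 fold change was -2.19 (SE 0.10), with an edgeR adjusted p of 4.12e-06. Hhip, which encodes a ligand-binding antagonist and is also induced by the pathway, fell from 521 ± 75.8 to 101 ± 18.4 CPM (log2 fold change -2.37, SE 0.15, adjusted p 1.84e-05). The transcription factor gene Gli1 fell from 125 ± 14.8 to 57.5 ± 11.9 CPM (log2 fold change -1.12, SE 0.15, adjusted p 0.00109). In mm10, Ptch1 lies on chromosome 13 (63508328 to 63573598), Hhip on chromosome 8 (79965851 to 80058006) and Gli1 on chromosome 10 (127329882 to 127341974). Of 13 tested hedgehog targets, 9 fell and none rose, both over all genes and adjusted over the list alone, with a median log2 fold change of -0.79. By camera, the adjusted p was 2.10e-12, and the adjusted p was 0.0663 with an estimated correlation. Bmp4 (-1.21) and Foxf2 (-0.79) were among the 9, as were Foxl1 (-1.34), Ccnd1 (-1.40) and Bcl2 (-0.34), which were chosen after their values were seen. Foxf1, a forkhead gene of lung mesenchyme, fell by 0.38 on the log2 scale with an edgeR adjusted p of 0.0376. That call ended, at adjusted p of 0.0771 to 0.131, without any IgG replicate or without 5E1 replicate 1 or 3, at 0.0515 with the stricter filter and at 0.0571 with length and GC offsets. Foxd1, Mycn and Rab34, named after their values were seen, did not pass.

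**Figure D2:**
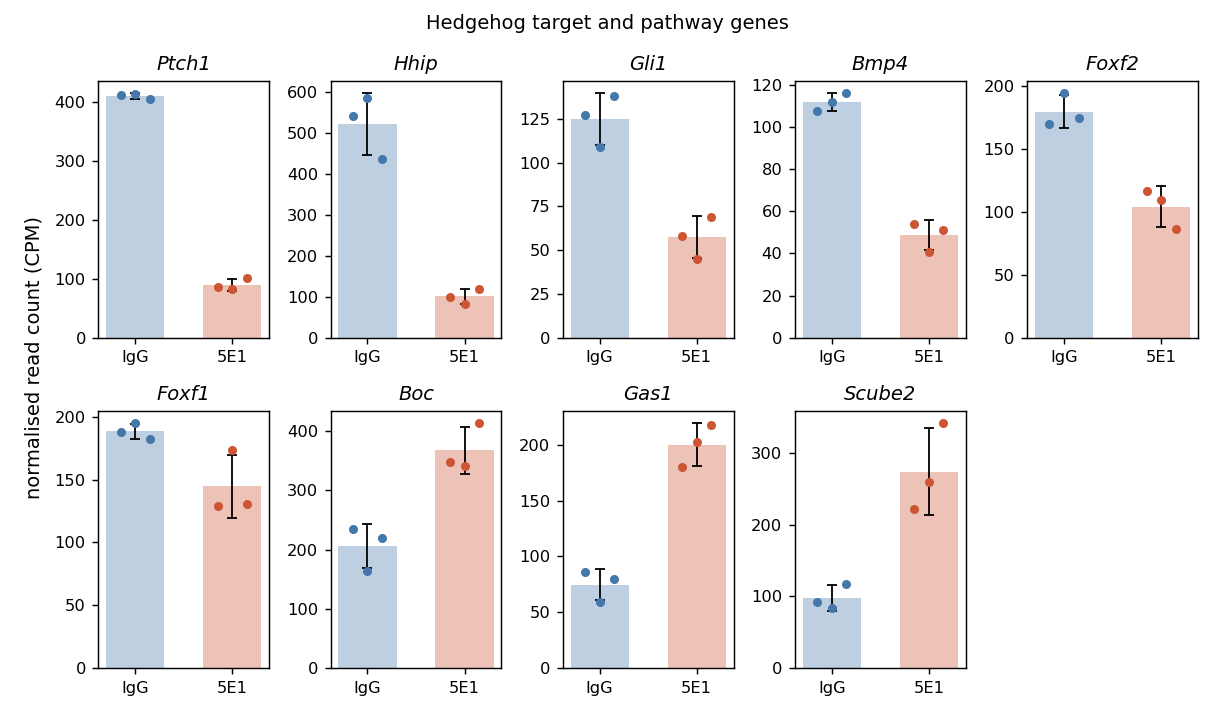
Normalised read counts in CPM on the vertical axes for 9 hedgehog target and pathway genes, with IgG in blue and 5E1 in red. Bars are means, error bars SD over 3 libraries and points single libraries, with all 5E1 values of Ptch1 between 82.1 and 101.9 CPM and all IgG values between 405.3 and 415.0 CPM.

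Among 20 tested hedgehog ligands, receptors and transducers, 4 rose and 1 fell (the same counts adjusted over the list alone), with 2 lower without 5E1 replicate 1 and 4 lower with library size alone. Gas1, a ligand co-receptor gene, rose from 74.8 ± 14.1 to 200.2 ± 19.2 CPM, and Scube2, which encodes a protein that helps release the ligand, from 97.48 ± 17.8 to 274.5 ± 61.3 CPM. Boc, another co-receptor gene, rose by a log2 fold change of 0.84, and Gpr161, a ciliary receptor gene that restrains the pathway, fell by 0.44. Disp1 also rose (0.62), chosen after its value was seen. The list as a whole was not called (camera adjusted p 0.427). Cells were sorted for the reporter of Pdgfra, so the level of this gene was read only in cells that passed that sort. Cells that lost or gained the reporter between groups would not show in it. Pdgfra itself measured 502 ± 77.5 CPM in IgG and 645 ± 73.3 CPM in 5E1 (log2 fold change 0.36, SE 0.13). Its edgeR adjusted p of 0.0742 did not pass. It did pass with DESeq2 (0.0292), with no low-count filter (0.0118) and with a term for libraries without Y-linked reads (0.0307). Pdgfrb rose by a log2 fold change of 0.40 and Pdgfd by 0.66, and Pdgfa (0.38, adjusted p 0.0829) did not pass, except without IgG replicate 3 (0.0446) and with the term for libraries without Y-linked reads (0.0377). The call of Pdgfrb ended without IgG replicate 2 (adjusted p 0.0572) or 3 (0.0841) and with library size alone (0.0884). Of 7 PDGF ligand and receptor genes 2 rose and none fell (4 and none adjusted over the list alone), and 1 rose without IgG replicate 2. The list was not called (camera adjusted p 0.0681), but was with DESeq2 (0.0112), limma-voom (0.0275) and no low-count filter (0.0230).

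Genes of the contractile apparatus of smooth muscle and myofibroblasts fell as a group. Acta2, which encodes alpha smooth muscle actin, fell from 1916 ± 101 CPM to 1056 ± 306 CPM (log2 fold change -0.86, SE 0.19, edgeR adjusted p 0.00938). Actg2 (-1.22), Synpo2 (-1.15), Cnn1 (-0.99) and Filip1l (-0.93) fell by similar amounts. Tagln fell by 0.48 (adjusted p 0.0257), a call that ended at 0.0513 to 0.0806 without any IgG replicate or without 5E1 replicate 2 or 3. Of 24 members, 17 fell and 2 rose (18 and 2 adjusted over the list alone), the 2 being Itga8 (0.89) and Mustn1 (0.90), named after their values were seen, of which 1 rose without IgG replicate 3. For this list camera gave an adjusted p of 5.10e-10, and the adjusted p was 0.339 with an estimated correlation. Markers of secondary crest myofibroblasts, the cells at the tips of growing septa, moved the same way in 14 of 20 members. Tgfbi, an extracellular matrix gene, fell from 5344 ± 565 to 2224.5 ± 88.0 CPM, Wnt5a from 673 ± 142 to 251 ± 15.2 CPM, and Igf1 from 759 ± 122 to 181 ± 44.2 CPM. Nkd1, a Wnt feedback gene, fell by a log2 fold change of -0.68. Aspn, Enpp2, Plxdc2 and Stc1 of the same list rose (log2 fold changes 0.95, 1.57, 0.89 and 1.26), named after their values were seen, and 2 members rose without IgG replicate 3. Adjusted over the list alone, 15 fell and 5 rose. Its camera adjusted p was 1.43e-07, and the adjusted p was 0.339 with an estimated correlation.

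Elastin ran against this direction. Eln, on chromosome 5 of mm10 (134702593 to 134747323), was the most abundant gene and rose from 27953 ± 4508 to 50523 ± 5589 CPM (SD, n = 3 each). Its log2 fold change was 0.85 (SE 0.19, edgeR adjusted p 0.00847, and 0.0506 without IgG replicate 3). Its share of gene counts was 2.93% ± 0.459 in IgG and 4.79% ± 0.392 in 5E1. Lox, which encodes the elastin crosslinking enzyme lysyl oxidase, rose from 652 ± 46.3 to 1621 ± 432 CPM, and Fbn2 rose by 0.72, whereas Loxl2, of the same enzyme family as Lox, fell by 0.82 on the log2 scale. Over the 22 elastic fibre genes 6 rose, 2 fell and 14 did not pass (7 and 2 adjusted over the list alone), and 3 rose and 1 fell without IgG replicate 2. The list was not called (camera adjusted p 0.136), but was with DESeq2 (0.0160) and without 5E1 replicate 2 (0.00587). Of 31 collagen genes 8 rose and 1, Col25a1 (-1.85), fell (14 and 1 adjusted over the list alone), with Col6a1 at 0.56, Col5a2 at 0.55 and Col8a2 at 0.94. Without IgG replicate 2 the calls of Col6a1 (edgeR adjusted p 0.0590) and Col5a2 (0.0546) ended, the latter also without IgG replicate 3 (0.0591). The collagen list had a camera adjusted p of 0.0108, and the adjusted p was 0.640 with an estimated correlation. Only 3 or 4 collagens rose without IgG replicate 2 (3), IgG replicate 3 (4) or 5E1 replicate 3 (4), and without the last 2 fell and the list's adjusted p was 0.0852. With library size alone 4 rose and 2 fell, with DESeq2 16 rose, and with no low-count filter 17 rose and 3 fell. Among 28 metalloproteinase and inhibitor genes 14 rose and 3 fell (17 and 3 adjusted over the list alone), with Mmp9 6.44-fold and Adamtsl2 3.94-fold higher. The camera adjusted p was 4.26e-05, and the adjusted p was 0.339 with an estimated correlation. Without IgG replicate 2 or 5E1 replicate 3 the number that rose was 8 or 9. Basement membrane genes moved both ways, with 3 higher and 4 lower of 28 (6 and 4 adjusted over the list alone, 1 higher without IgG replicate 2, 8 with DESeq2 and 9 with no low-count filter). Lama1 and Lama5 fell (-3.87 and -1.34), Frem2 fell (-1.68) and Lamb3 rose (1.27, with an edgeR adjusted p of 0.0531 without IgG replicate 1), and the list was not called (camera adjusted p 0.743). Mmp9 and Lamb3 are low, at 7.79 and 5.15 CPM in 5E1, and Mmp9 is also a neutrophil product.

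**Figure D3:**
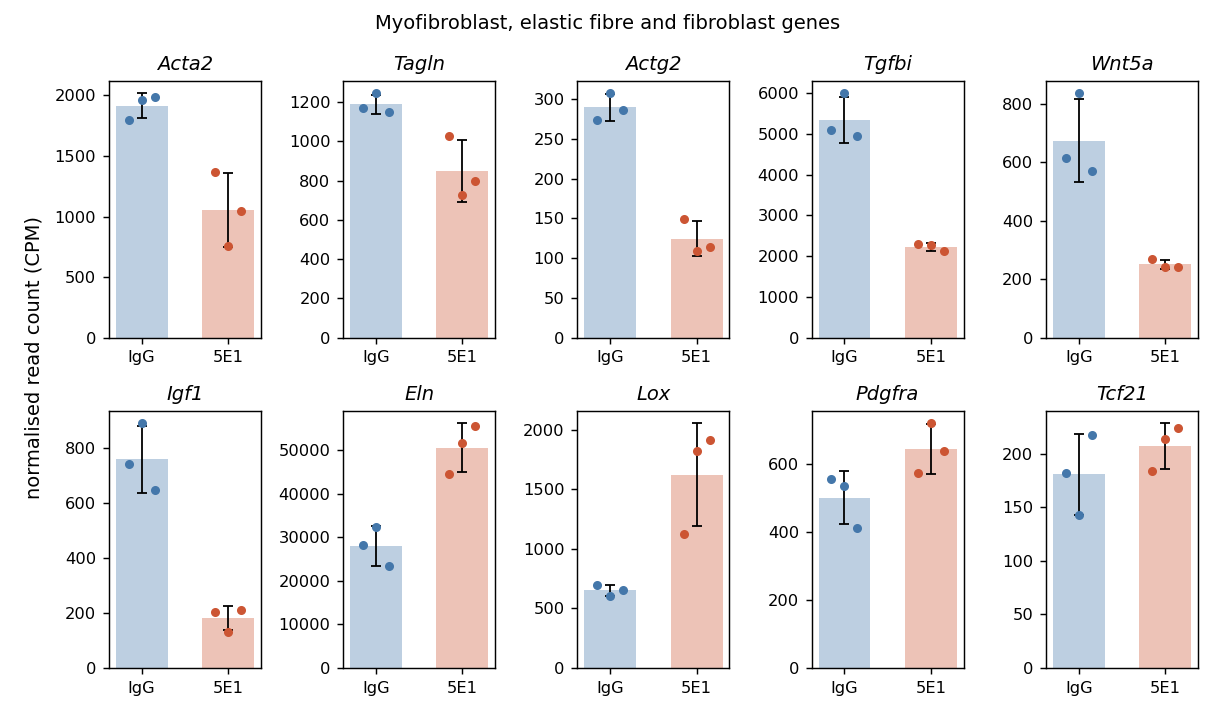
Normalised read counts in CPM on the vertical axes for 10 myofibroblast, elastic fibre and fibroblast genes, with IgG in blue and 5E1 in red. Bars are means, error bars SD over 3 libraries and points single libraries, and Eln rises from a mean of 27953 to 50523 CPM while Tgfbi falls from 5344 to 2224.5 CPM.

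Other fibroblast states moved too. Markers of adventitial fibroblasts, the cells around vessels and airways, rose in 12 of 22 members and fell in 1 (13 and 1 adjusted over the list alone). Mgp rose from 1158.5 ± 192 to 3189 ± 151 CPM, Gsn from 1382 ± 410 to 3942 ± 605 CPM, Pcolce2 by a log2 fold change of 1.44 and Igfbp6 by 2.44, and Cd34 fell by 0.49, named after its value was seen. No member fell without IgG replicate 1, 2 or 3 or 5E1 replicate 2, with the stricter filter or with length and GC offsets. By camera, the adjusted p was 2.95e-10, and the adjusted p was 0.339 with an estimated correlation. Without IgG replicate 3 or without 5E1 replicate 3, 7 members rose. Lipofibroblast and alveolar matrix fibroblast markers were split, with 8 of 26 higher and 4 lower (10 and 4 adjusted over the list alone, 4 higher without 5E1 replicate 3 and 2 lower without 5E1 replicate 2). Fabp4 (2.68) and Bmp3 (0.79) rose, Enpep (-1.11) and Slc27a6 (-1.36) fell, and Tcf21, a transcription factor gene of this lineage, measured 181 ± 37.7 and 207 ± 21.2 CPM (edgeR adjusted p 0.369). That list was not called (camera adjusted p 0.0681), but was with DESeq2 (0.00874), limma-voom (0.0340), no low-count filter (0.0346) and no robust estimation (0.0488). It was also called without IgG replicate 3 (0.00468) or 5E1 replicate 1 (0.00294). Pericyte markers rose in 7 and fell in 2 of 17 members, both also adjusted over the list alone. Postn, which is also on the TGF-beta list, rose from 1555 ± 113 to 3712 ± 438 CPM. Pdzd2 rose by 1.42, Ebf1 by 1.33 and Gucy1a3 by 0.52, and Trpc6 fell by 2.26 on the log2 scale. The call of Gucy1a3 ended without IgG replicate 1 (edgeR adjusted p 0.0507) or 3 (0.0525). The pericyte list had a camera adjusted p of 0.0225, which was 0.0623 without IgG replicate 3, and the adjusted p was 0.339 with an estimated correlation. Cartilage and bone genes fell in 7 of 15 members and rose in 1, Sox9 (0.72, named after its value was seen), with the same counts adjusted over the list alone, and none rose without 5E1 replicate 3. Ibsp (7.11 ± 2.54 CPM in IgG, 0.128 ± 0.102 in 5E1), Col9a1 (6.21 ± 4.07 and 0.300 ± 0.2502) and Runx2 (4.65 ± 0.560 and 1.97 ± 0.102) fell. Lect1 had 150 reads in IgG and 0 in 5E1, at least 52.9-fold lower against a floor of 3 reads over the group. For this list camera gave an adjusted p of 0.000134 and the adjusted p was 0.339 with an estimated correlation. The median log2 fold change was -1.20, it ran from -1.21 to -0.54 (without 5E1 replicate 2) with 1 library left out, and setting Lect1 to its bound did not move it. With the filter at 5 CPM none was called lower, the median was -0.24 and the camera adjusted p was 0.988.

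Among the 44 lists, genes of G2 and mitosis had the largest share of members that fell in the fit of all 6 libraries. Of 34 genes of G2 and mitosis 33 fell, with a median log2 fold change of -1.995 (34 adjusted over the list alone). Anln, which encodes a scaffold of the cleavage furrow, fell from 56.3 ± 0.740 to 19.4 ± 3.504 CPM (edgeR adjusted p 4.76e-05). Kif20a fell from 28.9 ± 3.24 to 7.35 ± 2.62 CPM, and Plk1 and Nek2 had log2 fold changes of -2.42 and -1.86. The exception, Top2a, fell short of the threshold at -2.33 (SE 0.63, adjusted p 0.0596), named after its value was seen. Of 32 genes of S phase and DNA replication 28 fell (29 adjusted over the list alone), with a median of -1.27. Log2 fold changes were -2.47 for Mcm10, -2.196 for Cdc6, -1.53 for Clspn and -0.79 for Mcm4, each a gene of replication licensing or of its checkpoint. The camera adjusted p was 8.17e-25 for G2 and mitosis and 5.12e-18 for S phase, and for each the adjusted p was 0.339 with an estimated correlation. Without IgG replicate 1, 2 or 3 or 5E1 replicate 3, G2 and mitosis genes that fell numbered 21, 20, 20 and 15, and with no low-count filter 21. S phase genes that fell numbered 18 without IgG replicate 2 and 17 without either IgG replicate 3 or 5E1 replicate 3.

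Cholesterol synthesis genes fell in 15 of 24 members and rose in none (17 and none adjusted over the list alone). Sqle, the squalene epoxidase gene, fell by 1.34 on the log2 scale, and Cyp51 (-1.23) and the sterol carrier gene Stard4 (-1.27) fell too. By camera, the adjusted p was 9.37e-13, and the adjusted p was 0.339 with an estimated correlation. Of 34 genes of fatty acid and triglyceride metabolism 9 rose and 2 fell (the same adjusted over the list alone), with Mgll at -1.38 and Lpin1 at 1.51. Without IgG replicate 2, 5 of them rose, with library size alone 6 fell, and the list was not called (camera adjusted p 0.245) except without 5E1 replicate 1 (0.0463). Glycolysis and hypoxia genes rose in 11 and fell in 2 of 30 members (12 and 4 adjusted over the list alone). Egln3, a prolyl hydroxylase gene, fell from 63.4 ± 7.78 to 10.6 ± 1.748 CPM, while Ddit4 (0.98), Ndrg1 (0.98) and Bnip3 (1.19) rose, and this list was not called either (camera adjusted p 0.361). Without IgG replicate 2 or 3 or 5E1 replicate 3, 6, 6 and 7 of them rose, 1 fell without IgG replicate 1 or 3 or 5E1 replicate 3, and 9 fell with library size alone. Oxidative phosphorylation genes had 1 of 39 members lower, Ndufa4 (-0.51), also adjusted over the list alone, with 2 lower without IgG replicate 2, 5E1 replicate 1 or 5E1 replicate 2, 11 lower with library size alone and 6 lower with length and GC offsets. Their camera adjusted p was 0.0497, and the adjusted p was 0.654 with an estimated correlation. The call was lost with RLE factors (0.0546), the stricter filter (0.178), the replicate number as a block (0.0628) and the run without sex-linked, erythroid and leukocyte markers (0.0507). It was also lost without IgG replicate 3 (0.135) or 5E1 replicate 2 (0.0674) or 3 (0.0852).

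In the IGF pathway 8 of 14 genes rose and 1, Igf1, fell (9 and 1 adjusted over the list alone), and 2 fell without 5E1 replicate 2. The binding protein genes Igfbp3 (6.54-fold), Igfbp6 (5.43-fold) and Igfbp2 (2.66-fold) were among the 8. For this list camera gave an adjusted p of 0.00475, and the adjusted p was 0.370 with an estimated correlation. TGF-beta pathway genes and targets rose in 6 and fell in 2 of 23 members (9 and 2 adjusted over the list alone), with Cilp at 2.81, Thbs1 at 0.97 and Tgfb2 at -0.77. The camera adjusted p was 0.0105, and the adjusted p was 0.445 with an estimated correlation. With library size alone 4 rose and 4 fell, 4 rose without IgG replicate 3 or 5E1 replicate 3, and 1 fell in every run that left out a library other than 5E1 replicate 1. In the retinoic acid pathway 6 of 18 genes rose and 3 fell (8 and 5 adjusted over the list alone). Cyp26b1, which encodes a retinoic acid degrading enzyme, rose from 4.87 ± 0.664 to 41.001 ± 9.37 CPM, Aldh1a1 from 29.5 ± 6.04 to 99.5 ± 25.5 CPM and Lrat by 1.70, while Rdh10 fell by 0.55. By camera, the adjusted p was 0.0326, and the adjusted p was 0.510 with an estimated correlation. That call was lost with limma-voom (0.157), without IgG replicate 2 (0.152) and without 5E1 replicate 3 (0.0852), and with library size alone 5 genes rose and 6 fell. Without IgG replicate 1 or 3 or 5E1 replicate 3, 1 gene fell.

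Over 27 genes of Wnt ligands, R-spondins and receptors 7 rose and 6 fell (8 and 7 adjusted over the list alone, camera adjusted p 0.998). Wnt11 fell from 216 ± 12.4 to 73.5 ± 12.9 CPM and Rspo2 by a log2 fold change of -1.55, whereas Rspo1, which is also a mesothelial marker, rose from 2.24 ± 0.397 to 11.03 ± 1.85 CPM. Among 22 canonical Wnt targets and feedback genes 4 rose and 5 fell, also adjusted over the list alone, with Tcf7 at -1.32, Apcdd1 at -0.88 and Lgr6 at -1.097 (camera adjusted p 0.378). In the BMP list 6 of 25 rose and 5 fell (6 and 6 adjusted over the list alone), with the antagonist gene Chrdl1 at 1.66 and the target Id3 at 0.83 (camera adjusted p 0.585, and 9 lower with library size alone). In the FGF list 7 of 22 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p 0.998). Fgfr2 fell from 78.2 ± 8.28 to 23.2 ± 3.68 CPM and Fgf18 by a log2 fold change of -1.05, and Fgf7 and Fgf2 rose by 0.78 and 0.47. Fewer FGF genes rose without IgG replicate 2 (3), IgG replicate 3 (4) or 5E1 replicate 3 (4). Of 16 Notch genes 2 rose, Notch2 (0.52) and Hey2 (0.97), the same adjusted over the list alone, and 4 rose without 5E1 replicate 2 or with no low-count filter. The Notch list (camera adjusted p 0.0621) was called with DESeq2 (0.0196), limma-voom (0.0173), no low-count filter (0.0454) and without 5E1 replicate 3 (0.0388). Of 16 YAP and TAZ targets 2 rose, Axl (0.62) and Nuak2 (1.03), and 2 fell, Ajuba (-0.56) and Tead1 (-0.41), with 4 and 2 adjusted over the list alone and 4 higher with length and GC offsets (camera adjusted p 0.644). Nuak2 lost its call without IgG replicate 1 (0.0939) or 2 (0.0839) or 5E1 replicate 3 (0.0704), and Tead1 without IgG replicate 2 (0.0672).

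Guidance genes of the semaphorin, ephrin and slit families rose in 7 and fell in 14 of 38 members (9 and 18 adjusted over the list alone, camera adjusted p 0.245). Unc5b (-1.13) and Robo2 (-0.70) fell and Sema3d (1.28) and Epha3 (0.75) rose, and without IgG replicate 2 the number that fell was 8. Transcription factor genes of lung mesenchyme rose in 6 and fell in 13 of 35 members (11 and 14 adjusted over the list alone, camera adjusted p 0.0838), a list that was called with DESeq2 (0.0196) and no low-count filter (0.0214, with 10 higher), with Sox11 at -1.01, Tbx3 at -0.76, Runx1 at -0.85 and Foxp2 at 1.104. Of 22 p53 targets and apoptosis genes 5 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p 0.585). Without IgG replicate 3, 3 rose, without IgG replicate 2 or 5E1 replicate 3, 1 fell, and with library size alone 5 fell. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 38.2 ± 6.45 to 99.4 ± 21.8 CPM, Sesn1 by 0.87 and Bcl2l11 by 0.42. The call of Bcl2l11 ended under library size alone (edgeR adjusted p 0.0556).

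Immediate early genes, which also rise during tissue dissociation, were higher in 25 of 29 members (27 adjusted over the list alone), none lower, with a median log2 fold change of 0.80. Nr4a3 rose from 95.1 ± 13.8 to 416 ± 102 CPM (edgeR adjusted p 0.000181), Nr4a2 by 1.74, Dusp1 by 1.19 and Fosl2 by 0.91. For this list camera gave an adjusted p of 4.55e-18, and the adjusted p was 0.339 with an estimated correlation. Cytosolic ribosomal protein genes rose in 33 of 44 members (43 adjusted over the list alone), by a median of 0.39, with Rps25 at 0.49 and Rpl23 at 0.46. With library size alone only 3 rose at a median of 0.25, and 14 rose without IgG replicate 1 and 8 without IgG replicate 2. The camera adjusted p was 2.43e-10, and the adjusted p was 0.370 with an estimated correlation. Chemokine, cytokine and complement genes rose in 13 of 27 members and fell in 1, Cxcl13 (-0.80, named after its value was seen), with 15 and 1 adjusted over the list alone. None fell without IgG replicate 1 or 3 or 5E1 replicate 1 or 3, and 2 fell without IgG replicate 2. Serping1, the complement C1 inhibitor gene, rose from 551 ± 105 to 1091 ± 154 CPM, C4b by 1.08 and Cxcl2 by 1.43. By camera, the adjusted p was 5.97e-06, and the adjusted p was 0.462 with an estimated correlation. Without IgG replicate 3 or 5E1 replicate 2 or 3, 7, 8 and 6 of these genes rose. Interferon response genes had 2 of 29 members higher, Oas3 (66 reads in 5E1 against 8 in IgG) and Ifih1 (0.80), and none adjusted over the list alone (camera adjusted p 0.983). Oas3 lost its call without IgG replicate 3 (0.0666) and Ifih1 in several settings, among them library size alone (0.0658), the replicate number as a block (0.0554), the term for libraries without Y-linked reads (0.0517) and the runs without IgG replicate 1 (0.108) or 2 (0.108) and without 5E1 replicate 2 (0.0924) or 3 (0.0707).

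**Figure D4:**
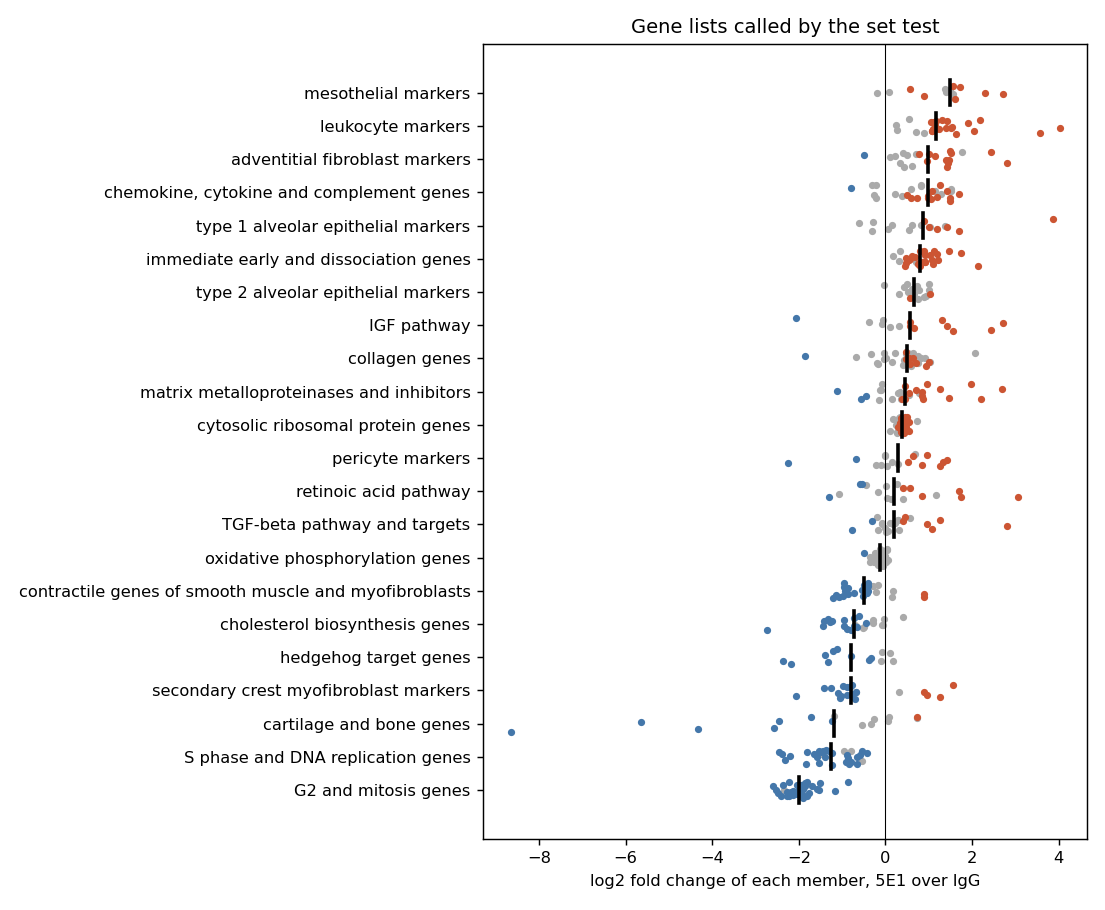
The horizontal axis is the log2 fold change of each member, 5E1 over IgG, for the 22 lists called by camera at the preset correlation, ordered by their median (black bar). Red and blue points are members called higher and lower, grey points did not pass, and the leftmost cartilage point is Lect1, a fitted value for a gene with 0 reads in 5E1. G2 and mitosis genes have the lowest median, -1.995, and mesothelial markers the highest, 1.49.

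Markers of cell types that the sort was meant to exclude differed between the groups as well. Leukocyte markers rose in 20 of 25 members (22 adjusted over the list alone) and fell in none, with a median log2 fold change of 1.17. S100a9 measured 6.21 ± 0.790 CPM in IgG and 74.3 ± 16.3 CPM in 5E1, H2-Aa 8.11 ± 2.31 and 30.4 ± 6.04 CPM, and Cd14 3.84 ± 1.30 and 17.5 ± 4.11 CPM. Lyz2, the most abundant member, measured 64.3 ± 7.20 and 119 ± 44.5 CPM (edgeR adjusted p 0.0662). It passed with DESeq2 (0.0281), limma-voom (0.0266), the stricter filter (0.0468), no robust estimation (0.0192) and without 5E1 replicate 3 (0.00176). The camera adjusted p of the list was 2.87e-20, and the adjusted p was 0.339 with an estimated correlation. These markers moved in the same direction as the chemokine and immediate early genes. Mesothelial markers rose in 7 of 13 members (9 adjusted over the list alone), none lower, and in 4 without IgG replicate 1 or without IgG replicate 2, and their median of 1.49 was 0.92 without 5E1 replicate 2. Upk1b measured 35.9 ± 6.36 and 109 ± 20.9 CPM and Cpe 53.9 ± 11.1 and 100.03 ± 9.22 CPM. Their camera adjusted p was 6.51e-06, and the adjusted p was 0.370 with an estimated correlation. Type 1 alveolar epithelial markers rose in 6 of 16 members (7 adjusted over the list alone, camera adjusted p 0.00475, and adjusted p 0.550 with an estimated correlation). Among them were Pdpn (0.90) and Ager (1.02), while the abundant members Emp2 (255 and 281 CPM) and Vegfa (188 and 152 CPM) did not pass. Vegfa passed as lower with library size alone (0.0493), no low-count filter (0.0114) and without 5E1 replicate 2 (0.0221), where 2 members of the list fell.

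Type 2 alveolar epithelial markers rose in 2 of 17 members, Abca3 (0.56) and Napsa (1.03), also adjusted over the list alone. The list's camera adjusted p was 0.0385, and the adjusted p was 0.695 with an estimated correlation. That call was lost with the stricter filter (0.0880), without sex-linked, erythroid and leukocyte markers (0.0558), without IgG replicate 1 (0.101) and without 5E1 replicate 2 (0.303). Of its members 1 rose without IgG replicate 1, 2 or 3 or 5E1 replicate 2, 7 rose without 5E1 replicate 3 and 5 with DESeq2 or no low-count filter. Sftpc measured 119 ± 4.88 and 183 ± 88.4 CPM (edgeR adjusted p 0.246, and 0.0497 without 5E1 replicate 3). Abca3 lost its call without IgG replicate 2 (0.0566) and with library size alone (0.0532), and Napsa without IgG replicate 1 (0.0997) or 3 (0.107) or 5E1 replicate 2 (0.0809). Airway epithelial markers had 1 of 14 members higher and none adjusted over the list alone (camera adjusted p 0.155). With DESeq2 2 were higher, with no low-count filter 3, and with the replicate number as a block none. Scgb1a1 measured 368 ± 125 and 514 ± 420 CPM (adjusted p 0.659), and was lower in 5E1 (-0.44) without 5E1 replicate 2. Endothelial markers had 2 of 24 higher, Tek (0.87) and Plvap (0.90), and 1 lower, Erg (-0.44), also adjusted over the list alone. Their camera adjusted p of 0.0723 passed with library size alone (0.0379), DESeq2 (0.00624), limma-voom (0.0173), no low-count filter (0.0293), the replicate number as a block (0.0346) and without 5E1 replicate 3 (0.000121), where 5 rose, as with no low-count filter. The call of Erg ended without IgG replicate 1 (0.128) or 2 (0.0532) or 5E1 replicate 2 (0.0599) or 3 (0.0583). Erythroid markers had none of 10 higher and 1 lower, Car2 (-0.60), also adjusted over the list alone (camera adjusted p 0.181, 0.0290 with DESeq2 and 0.0218 without 5E1 replicate 2). Car2 lost its call without IgG replicate 2 (0.0556), and 1, 2 and 4 members rose without 5E1 replicate 1, 2 and 3, 2 with DESeq2, 3 with limma-voom or no low-count filter and 5 with no robust estimation. Hbb-bs measured 104 ± 11.9 and 331 ± 279 CPM (adjusted p 0.146), and its log2 fold change of 1.68 was 0.72 without 5E1 replicate 3, where it passed (0.0183), as it did with limma-voom (0.0406) and no robust estimation (0.0260). Schwann and neuronal markers had 1 of 7 higher, Mbp (1.09), and 1 lower, S100b (-2.41), also adjusted over the list alone (camera adjusted p 0.705). S100b is also expressed in cartilage, and Mbp lost its call without IgG replicate 1 (0.103), 2 (0.109) or 3 (0.0737) and without 5E1 replicate 1 (0.0846) or 2 (0.112). It also lost it with library size alone (0.0550), limma-voom (0.0786), the replicate number as a block (0.0753) and the term for libraries without Y-linked reads (0.0508), and no member was then higher. Without IgG replicate 2, 2 members fell. None of 5 sex-linked genes passed, adjusted over the list alone or not (camera adjusted p 0.998).

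**Figure D5:**
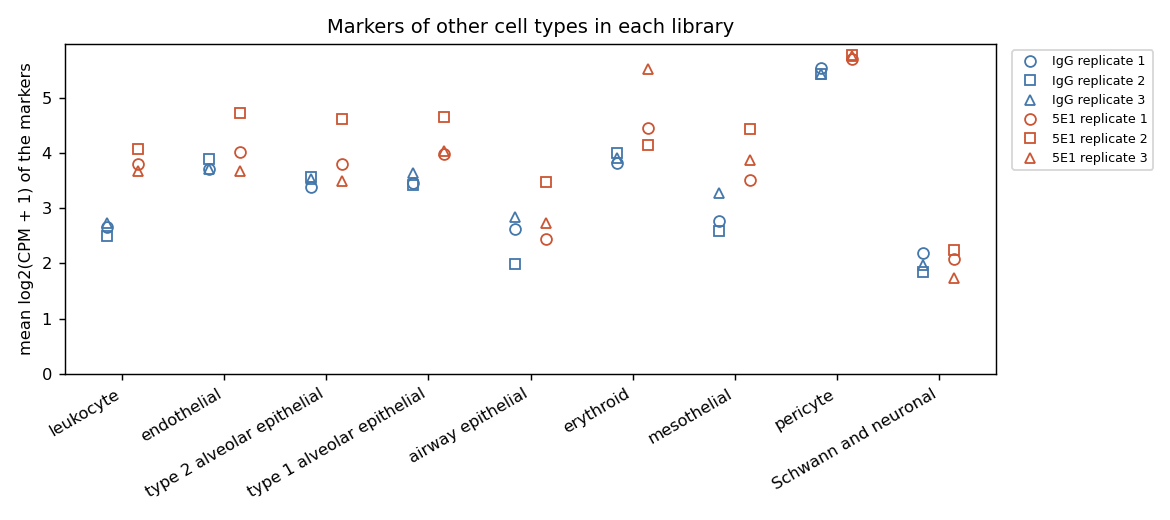
The vertical axis is the mean log2(CPM + 1) of the markers of 9 other cell types in each library, with IgG in blue and 5E1 in red and 1 symbol per replicate. Leukocyte markers lie between 2.49 and 2.73 in IgG and between 3.67 and 4.07 in 5E1, and 5E1 replicate 2 has the highest endothelial, epithelial and mesothelial values.

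The set test called 22 of the 44 lists, 14 higher and 8 lower in 5E1, and with an estimated correlation it called none, with 6 at an unadjusted p under 0.05. At the preset correlation it also called 13 to 22 lists in the 9 other ways of splitting the 6 libraries into 3 and 3, each of which sets 2 libraries of a group and 1 of the other against the rest and so keeps part of the difference. Directional fry called 19 lists and mixed fry 38. The median, mean and test of a list disagreed in sign for 8 lists, none of them called: hedgehog ligands and transducers, basement membrane, canonical Wnt, BMP, FGF, guidance, Schwann and sex-linked genes.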

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

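No explanation was tested for either of the values in this part. The summary lines that count reads not assigned to a gene were used in no comparison above, and a pair of them stood higher in every 5E1 library than in every IgG library. Reads in no annotated gene took 9.88% ± 0.883 (SD, n = 3) of uniquely aligned reads in 5E1 and 8.35% ± 0.593 (SD, n = 3) in IgG, with a two-sided exact permutation p of 0.1. Reads aligned to more than 1 place took 5.996% ± 0.280 of all reads in 5E1 and 5.33% ± 0.0656 in IgG, with a two-sided exact permutation p of 0.1. With 3 libraries against 3, 0.1 is the smallest p this test can give, so neither difference can pass 0.05.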

How the results depend on the processing

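The term for libraries without Y-linked reads, the length and GC offsets and the run without the 20 most abundant genes were chosen after seeing the data. Over all alternatives, the 186 named genes gave 3312 values, of which 3183 kept their direction and their side of the threshold, 62 fell short of it, 51 newly passed it and 16 changed sign. For the 43 lists other than hedgehog targets, the same counts were 753, 44, 29 and 29 of 855. No gene called in both a fit and its alternative changed direction.

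Leaving out 1 library gave 2305 to 3704 changed genes, 1221 to 1885 higher and 1073 to 1819 lower, and these runs have fewer samples. They shared 59.5% to 84.8% of the 3757 genes, gave 7 to 9 hedgehog targets with camera adjusted p of 2.63e-14 to 5.01e-10, and called 21 to 24 lists. With library size alone 3274 genes were lower, since without TMM factors the median of all genes moved by -0.14. Stricter thresholds gave fewer genes by construction: 1700 at an adjusted p under 0.01 (930 higher, 770 lower) and 2229 at a fold change of at least 1.5 (1292 higher, 937 lower). With an estimated correlation camera called 0 lists, 6 having an unadjusted p under 0.05, and hedgehog targets had an adjusted p of 0.0663. Mixed fry, which asks whether members change in either direction, called 38 lists. With the replicate number as a block 3220 genes, 22 lists and 9 hedgehog targets (camera adjusted p 1.27e-12) were called. Deviations from the group mean correlated at -0.106, -0.0365 and -0.0854 between libraries of the same number. This gave no sign that the numbers pair the samples, though 3 libraries per group cannot exclude it.

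Lists that changed direction were called in none of the settings named here, and the cause was not tested. Adjusted p was 0.699 for basement membrane genes with limma-voom (0.242 to 0.947 with 1 library left out). Wnt ligands had 0.924 with library size alone, 0.895 with DESeq2, 0.914 with no low-count filter, 0.870 with the block and 0.995 without the 20 most abundant genes (0.719 to 0.9996 with 1 library left out). FGF genes had 0.726 with limma-voom, 0.988 with the stricter filter, 0.843 with length and GC offsets and 0.895 with fry (0.753 to 0.997). Interferon genes had 0.794 with library size alone, 0.988 with the stricter filter and 0.985 with fry (0.160 to 0.9996). Schwann markers had 0.854 with limma-voom. Sex-linked genes had 0.671 with library size alone, 0.726 with limma-voom and 0.985 with fry (0.568 to 0.913).

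Genes that changed sign were not called there either, and the cause was not tested. With 1 library left out the log2 fold change ran from -0.81 to 1.19 for Xist, -0.95 to 0.20 for Uty, -0.55 to 0.61 for Ddx3y, -0.57 to 0.59 for Kdm5d and -0.44 to 0.80 for Scgb1a1. It was -0.0151 for Xist with the block and 0.47 for Uty with limma-voom. With library size alone it was -0.11 for Ddx3y, -0.12 for Kdm5d and -0.00431 for Emp2. Depth limits genes near 0 reads, such as Lect1 and Oas3, whose folds rest on few reads.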

Other observations

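The tests of leukocyte against other cell types' markers, neutrophil against macrophage genes, read share, secondary crest markers, length and GC offsets and glucocorticoid-responsive genes were chosen only after the result was seen. Neutrophil genes, chiefly of granules and receptors, had been in none of the 44 lists and were higher in 12 of 12 members in 5E1 (12 adjusted over the list alone). Of these, Mxd1 stood apart, at 33.8 ± 1.47 CPM in IgG and 43.3 ± 1.63 CPM in 5E1 (log2 fold change 0.36). Every other member had at most 2.92 CPM in IgG, so the call of Mxd1 says little about neutrophils. It was named after its value was seen. Mmp8, the neutrophil collagenase gene, measured 0.539 ± 0.319 CPM in IgG and 7.72 ± 0.820 CPM in 5E1, Ngp 1.58 ± 0.427 and 12.1 ± 5.42 CPM, and Lcn2 2.05 ± 0.913 and 12.6 ± 2.98 CPM. The camera adjusted p over the 4 added lists was 8.84e-14, and the adjusted p was 0.0326 with an estimated correlation (unadjusted 0.0117). The neutrophil list followed neutrophil genes already seen, so these p-values are no independent support. Macrophage genes were higher in 6 of 11 members (camera adjusted p 0.00104, and 0.186 with an estimated correlation), and 7 of the 11 are also in the leukocyte list. Lymphocyte genes were higher in 2 of 6 members (3 adjusted over the list alone, 0.0890, and 0.186 with an estimated correlation).

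Genes that respond to glucocorticoids were higher in 16 of 17 members (17 adjusted over the list alone), with a median log2 fold change of 1.25. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, rose from 20.2 ± 1.87 to 89.0 ± 27.8 CPM, Tsc22d3 from 80.6 ± 7.48 to 254 ± 60.9 CPM, Galnt15 by a log2 fold change of 3.35, Pdk4 by 2.44, Klf9 by 1.25 and Sgk1 by 1.24 (all edgeR adjusted p at most 0.000939). Mt2 did not pass (adjusted p 0.0720). For this list camera gave an adjusted p of 1.06e-23, and the adjusted p was 0.0326 with an estimated correlation. Zbtb16 prompted this list and is not in it. Retnlg, Hif3a and Ddit4, whose values were also known, were taken out of the neutrophil and glucocorticoid lists after results with them had been seen.

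The 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split gave 3757 changed genes and 9 hedgehog targets, and the highest of the other splits gave 0 and 0. Thus 1 of the 10 splits, the real split, gave as many of each. For called lists the real split gave 22 and the highest other 22, so 2 of the 10 splits gave as many. Every other split has IgG and 5E1 libraries on each side. The difference between the antibodies then adds to the spread within a side, which by itself lowers the number of genes called. These splits therefore do not show what groups without a difference would give, and no conclusion is drawn from the 0 and 0.

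Higher leukocyte markers in 5E1 were the first pattern weighed. A lower share of sorted mesenchyme would raise markers of all other types alike. Mean log2 fold changes (SD over members) were 1.41 ± 0.861 for leukocyte markers, 1.31 ± 0.813 for mesothelial, 1.16 ± 0.839 for erythroid, 0.841 ± 1.05 for type 1 alveolar, 0.716 ± 0.630 for airway, 0.665 ± 0.281 for type 2 alveolar, 0.584 ± 0.838 for Schwann (without S100b) and 0.537 ± 0.383 for endothelial markers. Per library, mesothelial markers had an unadjusted Welch p of 0.0369, higher in 5E1, and the other 6 types did not pass (0.0685 to 0.382). These p-values were not adjusted over the types, so the mesothelial one is weak. The change in leukocyte minus other markers per library had an adjusted p of 0.0146 against Schwann markers, which lie near the floor, and of at least 0.0808 against the other 6. Neutrophil genes rose by 2.24 ± 0.960 and macrophage genes by 0.891 ± 0.343, and their difference per library went from -0.662 ± 0.247 in IgG to 0.234 ± 0.249 in 5E1 (Welch p 0.0115). Neutrophil and macrophage genes thus did not rise alike. That comparison was chosen after neutrophil genes had been seen among the highest, and after leukocyte against other markers had not decided. It therefore cannot decide on a lower share of mesenchyme, which stays open, and mesothelial markers rose too. The leukocyte markers did not rest on 5E1 replicate 2, since 16 were called without it. A hypothesis is that more neutrophils, or RNA from them, came through the sort for live EGFP-positive cells, which should remove them. S100a9, at 74.3 CPM in 5E1, is far below Eln at 50523 CPM, and whether neutrophils were more numerous in the lungs was not tested.

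Lower contractile genes beside higher elastin were the second pattern. The 20 most abundant genes took 15.2% ± 0.869 of gene counts in IgG and 18.8% ± 2.02 in 5E1, a shift of -0.0626 on the log2 scale for all other genes. Scaled by library size alone, which leaves that shift in, 19 of 24 contractile genes were called lower and lay below it by over 2 SE. This argues against the read share of these 20 genes as the whole cause. In that scaling the median of all genes moved by -0.14, more than these 20 genes give, so the bound is lenient. With TMM, where the median of all genes was 0.000873, 17 contractile genes fell and the list's median was -0.50. Length and GC offsets gave 17 contractile genes lower, which argues against these biases as the whole cause. A smaller share of myofibroblasts among the sorted cells cannot be told apart from lower expression per cell, because 14 secondary crest markers were lower and 4 higher in bulk RNA. The antibody, which is the difference the design names, stays open with it.

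Higher glucocorticoid-responsive genes were the third pattern. Their median of 1.25 was 1.273 with length and GC offsets, which argues against these biases as the whole cause. The list was written and trimmed after values of such genes had been seen, so how far the choice of genes made the pattern is open. A candidate explanation is a difference in glucocorticoid exposure or in stress between the groups, which no label describes and which was not tested.

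IgG replicate 3 and 5E1 replicate 1 held under 1 CPM of each of Ddx3y, Kdm5d, Eif2s3y and Uty, with Xist at 1038.5 and 1510 CPM. The other libraries held 96.9 to 111 CPM of Ddx3y, and their Xist measured 309 and 316 CPM in IgG replicates 1 and 2 and 175 and 460 CPM in 5E1 replicates 2 and 3.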
